A study of Homo sapiens with 16 samples.

How the data were processed

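The series holds ChIP and input libraries of HEK293 cells for 4 conditions, with 8 ChIP samples and 8 input samples and 2 replicates of each kind per condition. Per the labels' protocols, starved cells were kept in 0.1% serum for 18.5 to 20 h, and induced cells then received 18% serum for 15 min. Flavopiridol was given at 1 µM from 1 h ahead of the induction, per the labels' protocols. Chromatin was sheared by sonication, and the libraries were read from a single end over 40 nt, per the labels' protocols. Groups were taken from the sample titles and the inhibitor label. Which code of an inhibitor was starved and which was induced was not given in the sources used here, and it was not inferred from the data.

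The files analysed were 4 peak lists in narrowPeak format, 1 per condition code, on hg19 per the file headers. The submitters' processing notes name CASAVA, Trimmomatic 0.32, Bowtie 1.1.2, Picard, MACS2 2.1.1.20160309 and bedtools, with no role or setting for any of them. Whether the reads of both replicates were pooled for a list, whether the input libraries served as control, the thresholds of the peak caller and the treatment of duplicate reads were not given in the sources used here. A row of a list is a summit, and several summits can share an interval. The deposited fold enrichment is a linear ratio at the summit, and the deposited −log10 p and −log10 q are the values of the authors' peak caller. The deposited score was the whole part of 10 times the −log10 q in every row. The lowest deposited −log10 q was 1.31 to 1.32 in the 4 lists. These steps affect the measurements in that a list depends on depth: more reads can let weaker regions pass and can join neighbouring peaks into longer intervals.

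Intervals with the same chromosome, start and end were counted once and took the values of their summit with the highest −log10 q. From the deposited fold and −log10 p, whole reads at the summit and the local background were recovered, with the fold as reads plus 1 over background plus 1 and the p-value as a Poisson tail. The recovered pair matched the deposited −log10 p within 0.0005 in 100% of the rows of each list. The lowest background of a list was taken as a measure of its depth, an interpretation of the values that no label states. With the inputs as control, the local background, the fold and the ratios of depth would also depend on input reads and on how they were scaled. Over the 25 intervals of at least 2 kb in DMSO-S2, the median background was 1 times the lowest of the list. That argues against a background taken from the ChIP reads around them in that list. The lists alone do not show which control was used or how it was scaled. The lowest background was 0.151 reads in DMSO-S1, 0.287 in DMSO-S2, 0.138 in flavopiridol-S5 and 0.268 in flavopiridol-S6. The fewest reads at a summit with that background were 3 in DMSO-S1 and flavopiridol-S5 and 4 in DMSO-S2 and flavopiridol-S6. An interval with a background of at least 10 times the lowest at any summit was called high-background.

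Lists were compared by overlap of at least 1 bp, with the Jaccard index in bp and the mean over 100 random placements within chromosomes. Overlapping intervals of the 4 lists were merged into regions, and each region was classed by the lists with a peak in it. Shares carry exact Clopper-Pearson 95% intervals. Peaks are not independent draws, so these intervals cover counting error only. The lists hold no values per replicate, so no test between conditions was run, and fold and −log10 q were used to describe, rank and filter within a list. The recovery, overlap and merging steps were tested on simulated lists of the same length. The reads were recovered in 99.99% to 100% of rows of a list and the shared intervals in 100%. The simulated folds and p-values came from the formula that the recovery inverts, so the simulation checks the inversion and not the formula. Its backgrounds did not reach the highest ones recovered from the lists.

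Regions named in the text were fixed by a rule before the data were examined. For DMSO and for flavopiridol, they were 5 regions held by both lists of the inhibitor and neither of the other, ranked by the higher −log10 q of the 2 lists. The rule also took 5 of best mean rank in all 4 lists, and 5 of highest −log10 q in each list without the other list of its inhibitor. Ties went to the higher fold and then to position. Long intervals and windows of the genome were chosen after the values had been seen. Alternatives fixed before the data were examined were a −log10 q of at least 5, equal numbers of peaks, chromosomes 1 to 22, X and Y, reciprocal overlap of 50%, a distance of 1 kb, and merging over 1 kb and 5 kb. Removal of high-background intervals, removal of 2 windows of chromosome X and joining of peaks up to 1 kb apart within a list were added later.

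The planned comparisons with gene positions, gene classes and 13 fixed gene lists were not run, because the gene table at hand is on GRCh38 and the files are on hg19. Input libraries had no list of their own among the files analysed here. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with plots from matplotlib 3.10.9.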

Results

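HEK293 cells, an established line derived from human embryonic kidney, were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody labelled S2 Pol II. That shorthand usually names RNA polymerase II phosphorylated on serine 2 of the repeats of its C-terminal domain, a form found on elongating polymerase. The series title names P-TEFb, the kinase complex of CDK9 and a cyclin that places this mark, and flavopiridol is an inhibitor of CDK9. The design crossed serum starvation or serum induction with DMSO or flavopiridol. Each of the 4 conditions had 2 ChIP samples and 2 samples of input DNA, which makes 16 samples. The labels assign the condition codes S1 and S2 to DMSO and the codes S5 and S6 to flavopiridol. They do not say which code of a pair was starved and which was induced, so the pairs were compared by code. The lists are called DMSO-S1, DMSO-S2, flavopiridol-S5 and flavopiridol-S6 here, and the code S2 has no relation to the name of the antibody.

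The peak lists gave 1 set of values per condition and none per replicate. No spread between replicates could be computed, and no difference between conditions carries a p-value. Exact Clopper-Pearson 95% intervals are given for shares, and they cover counting error only. Library totals were not given in the sources used here. The lowest local background at a summit, recovered from the deposited values, was taken as a measure of depth. Whether the input libraries served as the control of the peak caller was not given in the sources used here, and with such a control the background would also reflect input reads and their scaling. The lowest background was 0.151 reads in DMSO-S1, 0.287 in DMSO-S2, 0.138 in flavopiridol-S5 and 0.268 in flavopiridol-S6. By this measure DMSO-S1 had 0.526 times the depth of DMSO-S2, and flavopiridol-S5 had 0.516 times that of flavopiridol-S6. The pairs closest in depth were DMSO-S1 with flavopiridol-S5, at a ratio of 0.917 of the latter to the former, and DMSO-S2 with flavopiridol-S6, at 0.935. All positions are on hg19 and count from 1. No gene annotation of that build was used, so regions are named by position and not by gene.

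The first comparison describes how many peak intervals were called in each condition, which is not a measure of the amount of signal. DMSO-S1 held 9504 peak intervals, DMSO-S2 held 5223, flavopiridol-S5 held 7476 and flavopiridol-S6 held 6633. Together the intervals covered 2296 kb in DMSO-S1, 1580 kb in DMSO-S2, 1997 kb in flavopiridol-S5 and 2091 kb in flavopiridol-S6. The order of the lists by number changed with the threshold. At a −log10 q of at least 5, flavopiridol-S6 held 3819 intervals, flavopiridol-S5 2351, DMSO-S2 1833 and DMSO-S1 1627. At a −log10 q of at least 10 the counts were 1415, 609, 408 and 222 in the same order. As a share of its list, that class made up 21.3% of flavopiridol-S6 (95% interval 20.4 to 22.3), against 7.81% of DMSO-S2 (7.10 to 8.57), the list closest to it in depth. In flavopiridol-S5 the share was 8.15% (7.54 to 8.79), and in DMSO-S1, the list closest to it in depth, it was 2.34% (2.04 to 2.66). In both pairs of similar depth the flavopiridol list therefore had the larger share of high-q intervals, with intervals apart.

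Fold enrichment and −log10 q at a summit are the authors' values and describe peaks within a list. The median fold over an interval's strongest summit was 4.98 in DMSO-S1, 5.44 in DMSO-S2, 5.21 in flavopiridol-S5 and 6.31 in flavopiridol-S6. The median −log10 q was 3.37, 3.82, 4.16 and 5.59 in that order. Most peaks rested on few reads. The median number of reads at a summit was 5 in DMSO-S1 and flavopiridol-S5, and 7 in DMSO-S2 and flavopiridol-S6. The median interval length was 194 bp, 223 bp, 209 bp and 267 bp in DMSO-S1, DMSO-S2, flavopiridol-S5 and flavopiridol-S6. In DMSO-S1, 50.7% of the intervals had the shortest length in the list, 194 bp.

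Long intervals set DMSO-S2 apart, a class described after the lengths had been seen. DMSO-S2 held 70 intervals of at least 1 kb, 1.34% of its list (1.05 to 1.69). Flavopiridol-S6 held 26, or 0.392% (0.256 to 0.574), DMSO-S1 held 14, or 0.147% (0.0806 to 0.247), and flavopiridol-S5 held 8, or 0.107% (0.0462 to 0.211). At 2 kb or more the count was 25 in DMSO-S2 and 1 in each of the other lists. That 1 interval lay on chromosome 6 near position 58776261, where the recovered background was over 10 times the lowest of the list, and a matching interval accounted for 1 of the 25 in DMSO-S2. Without it, 24 intervals of at least 2 kb were left, all in DMSO-S2. When peaks up to 1 kb apart were joined within a list, the counts at 1 kb or more became 213 in DMSO-S1, 258 in DMSO-S2, 185 in flavopiridol-S5 and 282 in flavopiridol-S6. At 2 kb or more they became 32, 73, 16 and 30, so by count the excess of DMSO-S2 was seen at 2 kb after joining and not at 1 kb. These are counts and not shares of a list, and DMSO-S2 held the fewest intervals before joining.

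**Figure D1:**
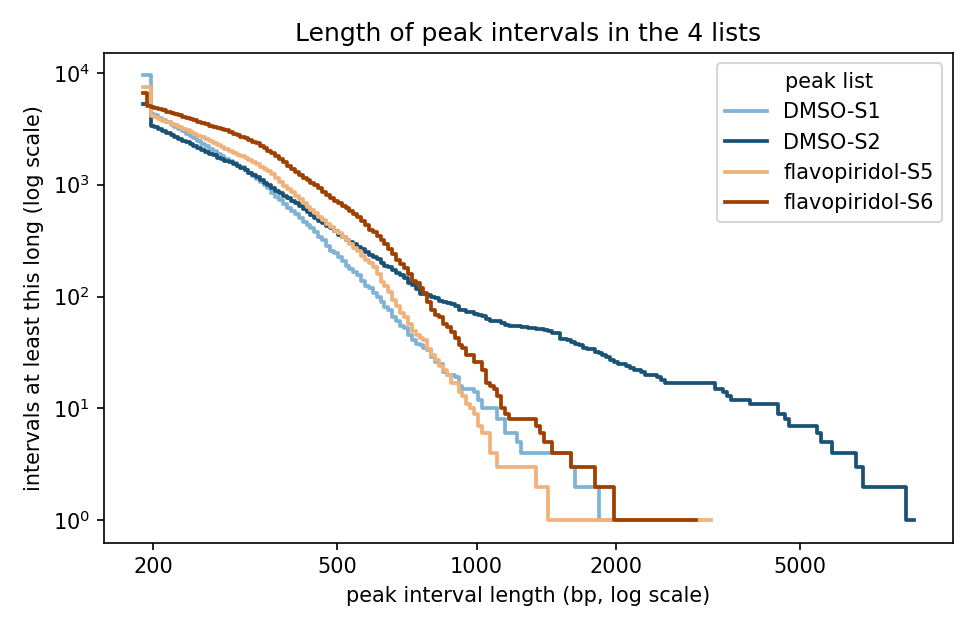
Number of peak intervals (vertical axis, log scale) that are at least as long as the length on the horizontal axis (bp, log scale), with a line for each of the 4 peak lists. DMSO-S2 holds 70 intervals of at least 1 kb and 25 of at least 2 kb, and each other list holds 1 of at least 2 kb.

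The longest of these lay on chromosome 19 from 45971095 to 45979947, an interval of 8853 bp with 17 summits and a highest −log10 q of 62.9. Flavopiridol-S6 held a single interval inside it, which covered 456 bp, or 5.15%, at its left end. DMSO-S1 and flavopiridol-S5 held none there. On chromosome 12, the interval from 52444737 to 52451533 measured 6797 bp, and flavopiridol-S6 covered 619 bp of it while DMSO-S1 and flavopiridol-S5 covered none. On chromosome 5, from 137801000 to 137806805, flavopiridol-S6 covered 1278 bp of 5806 bp in 2 intervals. The interval on chromosome 1 from 212787561 to 212792279, with a length of 4719 bp, was met by no interval of another list. It was part of a run of neighbouring DMSO-S2 intervals that began at 212781936. The first interval of that run, up to 212785179, was met by each of the other lists, and flavopiridol-S6 covered 19.9% of it. A different layout was seen on chromosome 11 from 65190108 to 65198453, where DMSO-S1 held 9 separate intervals that covered 47.9% of 8346 bp. There flavopiridol-S5 covered 6.89% and flavopiridol-S6 7.14%, each with 1 interval.

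Over the 24 long DMSO-S2 intervals without high background, which spanned 101 kb, DMSO-S1 covered 12.2%, flavopiridol-S5 3.46% and flavopiridol-S6 12.1%. Flavopiridol-S6 met 18 of the 24, DMSO-S1 met 13 and flavopiridol-S5 met 8, but none of them held an interval of 2 kb there. DMSO-S1 held 11 intervals of at least 1 kb without high background. Its longest lay on chromosome 6 from 26156429 to 26158235, with a length of 1807 bp, and others lay on the same chromosome at 26031310 and 26055709. DMSO-S2 met all 11, and it covered 81.8% of their length, against 41.2% for flavopiridol-S5 and 39.3% for flavopiridol-S6.

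**Figure D2:**
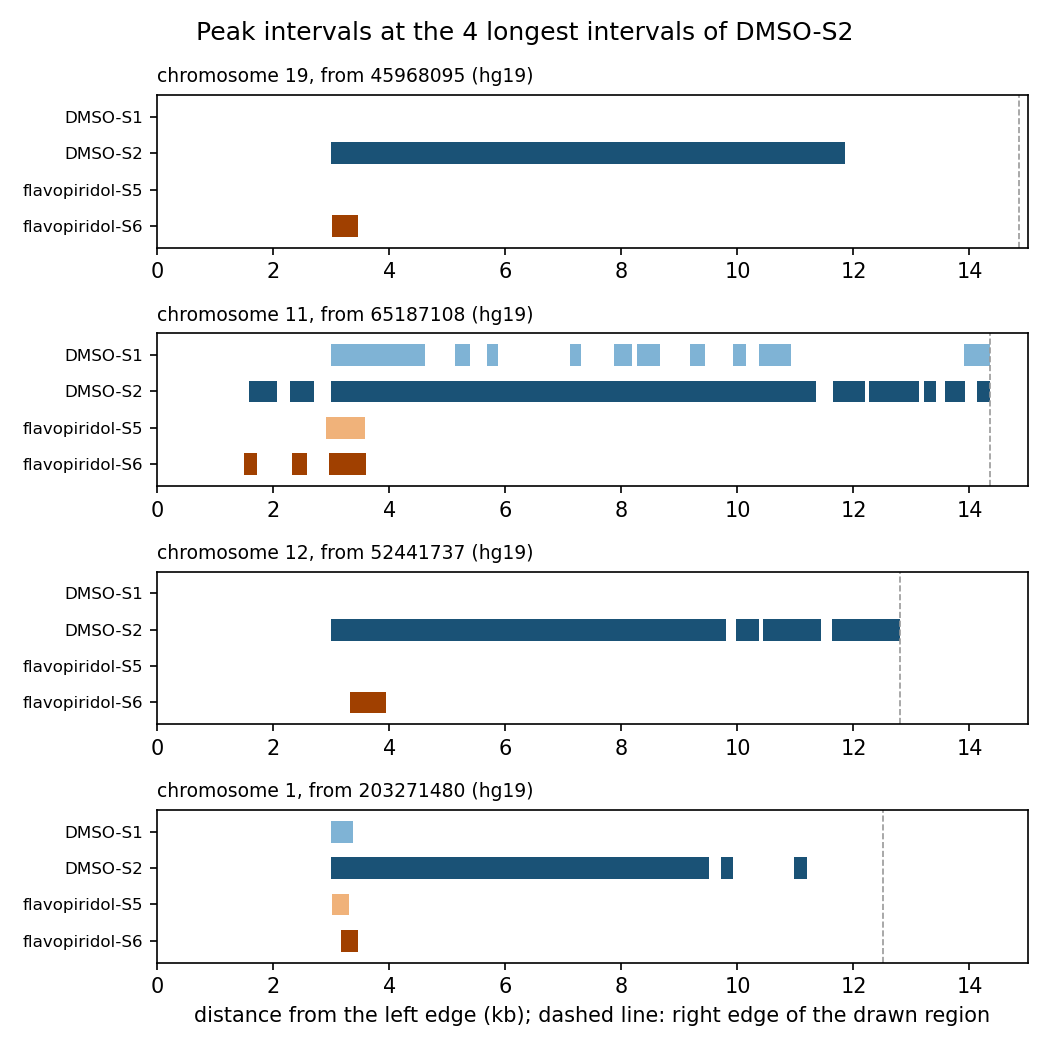
Peak intervals of the 4 lists (bars, 1 row per list) at the 4 longest intervals of DMSO-S2, with 3 kb drawn on both sides; the horizontal axis is the distance from the left edge in kb, and bars are clipped at the edges. On chromosomes 19 and 12 only flavopiridol-S6 holds another interval under the long DMSO-S2 interval, covering 456 bp and 619 bp, while on chromosome 11 DMSO-S1 holds 9 intervals under it.

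The second comparison asked how far the conditions marked the same places, with an overlap of at least 1 bp counted as shared. The flavopiridol lists overlapped most. Of the flavopiridol-S6 intervals, 45.6% (44.4 to 46.8) met flavopiridol-S5, and the Jaccard index in bp was 24.96%. Of the DMSO-S2 intervals, 30.4% (29.1 to 31.6) met DMSO-S1, with a Jaccard index of 11.1%. Between inhibitors at similar depth, 22.9% (21.99 to 23.9) of flavopiridol-S5 met DMSO-S1, and 35.9% (34.6 to 37.3) of DMSO-S2 met flavopiridol-S6. In the remaining pairs, 30.0% (28.9 to 31.1) of flavopiridol-S6 met DMSO-S1, and 29.1% (27.8 to 30.3) of DMSO-S2 met flavopiridol-S5. The Jaccard index between inhibitors was 9.95% for S1 with S5, 11.3% for S2 with S5, 12.2% for S1 with S6 and 15.2% for S2 with S6. By this index the DMSO pair exceeded only the pair of S1 with S5. Over 100 random placements of the intervals within their chromosomes, the mean share lay between 0.119% and 0.223% for the 12 ordered pairs.

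Overlap rose with the strength of the peak. Among DMSO-S2 intervals with a −log10 q of 10 or more, 73.0% (68.5 to 77.3) met DMSO-S1, against 21.2% (19.8 to 22.6) of those below 5. For flavopiridol-S6 against flavopiridol-S5 the shares were 82.6% (80.5 to 84.6) and 23.3% (21.8 to 24.9). When each list was reduced to its 5223 intervals of highest −log10 q, 45.5% of flavopiridol-S6 met flavopiridol-S5 and 23.1% of DMSO-S2 met DMSO-S1.

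The third comparison set DMSO against flavopiridol over merged regions. Joining overlapping intervals of the 4 lists gave 20567 regions, and 15922 of them, or 77.4%, held a peak in 1 list only. Both flavopiridol lists and neither DMSO list held a peak in 1115 regions, and the reverse was true of 402 regions, a ratio of 2.77. Regions held by 1 list of each inhibitor and no other list numbered 323 for DMSO-S1 with flavopiridol-S6 and 295 for DMSO-S2 with flavopiridol-S6. They numbered 196 for DMSO-S1 with flavopiridol-S5 and 137 for DMSO-S2 with flavopiridol-S5. All 4 lists held a peak in 842 regions. With only peaks of −log10 q of at least 5 the ratio was 7.08, and the number of DMSO-only regions fell to 124. That filter also drops weaker peaks of the other inhibitor. Regions at that threshold in both lists of an inhibitor, with no peak of the other at any strength, numbered 441 for flavopiridol and 71 for DMSO. The ratio was 2.89 with equal numbers of peaks, 2.49 with merging over 1 kb and 2.44 over 5 kb.

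**Figure D3:**
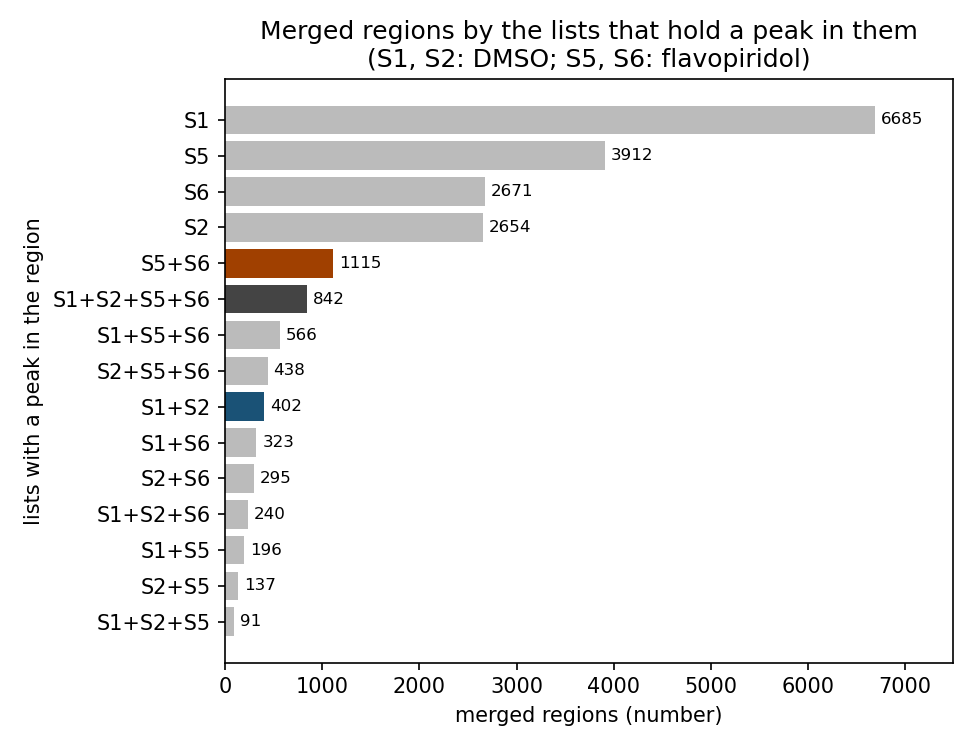
Number of merged regions (horizontal axis) for each of the 15 combinations of lists that hold a peak in the region (vertical axis). The bar for both flavopiridol lists alone reaches 1115 regions, that for both DMSO lists alone reaches 402, and that for all 4 lists reaches 842.

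Ranked by the stronger of the DMSO lists, the first DMSO-only region lay on chromosome 7 from 5565028 to 5566923, with a −log10 q of 47.0 in DMSO-S2 and 3.56 in DMSO-S1. The next was on chromosome 11 from 65272041 to 65275544, a region of 3504 bp with 40.9 in DMSO-S2 and 5.64 in DMSO-S1. Others lay on chromosome 6 from 139695495 to 139695945, on chromosome 21 from 28216424 to 28217834 and on chromosome 18 from 57571204 to 57572829. All 5 were led by DMSO-S2, and the region on chromosome 6 was the only one with a −log10 q above 8 in DMSO-S1, at 8.30. Merging over 1 kb already joined the regions on chromosomes 7 and 11 to a flavopiridol peak. Close to the region on chromosome 7, in the DMSO-S2 interval from 5568354 to 5570432, the −log10 q was 126 in flavopiridol-S6 and 14.1 in flavopiridol-S5. Of these 5 regions, 2 were still free of flavopiridol peaks when peaks up to 5 kb apart were merged, those on chromosomes 6 and 21. With peaks of −log10 q of at least 5, the regions on chromosomes 6 and 11 kept a peak in both DMSO lists, and 3 of the 5 did not.

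Among flavopiridol-only regions, the highest −log10 q was on chromosome 17 from 79670095 to 79670806, with 48.3 in flavopiridol-S6 and 32.1 in flavopiridol-S5. The region on chromosome 9 from 140099857 to 140100411 had 47.7 and 28.2. Those on chromosome 20 from 3140262 to 3140665, chromosome 12 from 49245711 to 49246098 and chromosome 5 from 37370953 to 37371695 had 40.4, 35.9 and 35.2 in flavopiridol-S6. These 5 regions were 388 to 743 bp long, while the DMSO-only 5 ranged from 451 to 3504 bp. That contrast holds for the named regions only. The median length was 387 bp over all 1115 flavopiridol-only regions and 381 bp over all 402 DMSO-only regions. Merging up to 1 kb left 4 of the 5 without a DMSO peak. Merging up to 5 kb left 3 of the 5 without one, on chromosomes 20, 12 and 5.

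Of the regions shared by all 4 lists, the best mean rank belonged to chromosome 11 from 62608705 to 62609578. Its −log10 q was 129 in DMSO-S1, 164 in DMSO-S2, 94.8 in flavopiridol-S5 and 154 in flavopiridol-S6. The regions on chromosome 1 from 121483992 to 121485583 and on chromosome 7 from 61968793 to 61969709 ranked next, and there the recovered background was 66.2 to 107 times the lowest of the list. The last 2 of the 5, on chromosome 1 from 149223599 to 149224725 and on chromosome 17 from 56736121 to 56736862, had a background of 1.06 to 2.999 times the lowest.

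The fourth comparison set the codes of an inhibitor against each other, which differ in serum state in an order the labels do not give. DMSO-S1 held a peak in 7770 regions without one from DMSO-S2, DMSO-S2 held 3524 without DMSO-S1, and both held 1575. For flavopiridol, S5 held 4336 regions without S6, S6 held 3529 without S5, and both held 2961. With peaks of −log10 q of at least 5 the counts were 1110 for DMSO-S1 and 1313 for DMSO-S2, and 840 for flavopiridol-S5 and 2302 for flavopiridol-S6. The larger side thus changed in both pairs at the stricter threshold, and the lists of each pair differed in depth.

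The 5 regions of highest −log10 q in DMSO-S2 and absent from DMSO-S1 included the long intervals on chromosome 5 at 137801000, chromosome 12 at 52444737 and chromosome 19 at 45971095. Their −log10 q in DMSO-S2 was 94.3, 87.7 and 62.9. The other 2 lay on chromosome 12 from 52453362 to 52454791 and on chromosome 1 from 212794354 to 212796844, with 53.4 and 39.4, and no other list held a peak in them. Both continued runs of neighbouring DMSO-S2 intervals, which began at 52444737 on chromosome 12 and at 212781936 on chromosome 1. Other lists did hold peaks in the first interval of each run. The regions on chromosome 5 at 137801000 and chromosome 1 at 212794354 gained a DMSO-S1 peak when peaks up to 1 kb apart were merged. In the opposite direction the values were lower. DMSO-S1 had 22.2 on chromosome 11 from 62420522 to 62420983, and 13.5 to 15.2 in the next 4 regions, on chromosome 11 at 67236305 and 62648159 and on chromosome 1 at 91966301 and 23037206.

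For flavopiridol, the region on chromosome 5 from 137801000 to 137806805 was also the strongest in flavopiridol-S6 without flavopiridol-S5, at a −log10 q of 60.6. It was followed by chromosome 1 from 86046261 to 86050905 with 38.2, chromosome 19 from 18682511 to 18682915 with 32.0 and chromosome 5 from 162864474 to 162865006 with 29.7. The last of the 5 was chromosome 5 from 172192956 to 172198384 with 27.4. In 3 of these 5 regions DMSO-S2 held an interval of over 4 kb, while the longest of flavopiridol-S6 there was 556 to 978 bp. The 5 strongest of flavopiridol-S5 without flavopiridol-S6 had a −log10 q of 14.1 to 17.0. They lay on chromosome 16 at 1660444, chromosome 19 at 58011183, chromosome 2 at 96068227, chromosome 1 at 9241964 and chromosome 11 at 124670110.

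By chromosome, the share of intervals was higher in both DMSO lists than in both flavopiridol lists on 5 of 24 nuclear chromosomes, and lower on 6. Random order would put 33.3% of chromosomes, or 8 of 24, in these 2 classes together, so the 8 is not an expectation for either direction alone. Chromosome X had 4.40% (3.99 to 4.83) of DMSO-S1 and 4.86% (4.30 to 5.48) of DMSO-S2, against 3.73% (3.31 to 4.19) of flavopiridol-S5 and 3.36% (2.94 to 3.82) of flavopiridol-S6. Without 2 windows of 100 kb, from 73000001 and from 134000001, the shares were 4.03%, 3.76%, 3.72% and 3.35% in the same order. These windows were picked after the data had been seen, for their excess of DMSO intervals, so leaving them out lowers the DMSO shares by construction. With peaks of −log10 q of at least 5 the shares were 3.13%, 4.80%, 2.21% and 2.46%. Chromosome 3 had 3.18% of both DMSO lists, against 4.17% and 3.93% of the flavopiridol lists. On no chromosome were the 95% intervals of both DMSO lists apart from those of both flavopiridol lists.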

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

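All tests in this part were chosen after the result had been seen. The mitochondrial chromosome, which the comparison by chromosome leaves out, held 12 intervals with 18 summits in DMSO-S2, covering 6107 bp between positions 207 and 16303. DMSO-S1 and flavopiridol-S5 held 1 interval each there, and flavopiridol-S6 held 0. The result was picked out as a signal outside the main measurement. The local background at these summits had a median of 111 times the lowest of DMSO-S2, and the fold lay between 1.78 and 2.93. The highest fold was 1.64 times the lowest, so no summit stood out, as mitochondrial DNA carried along the whole molecule would give. The background was raised alike at the single summits of DMSO-S1, at 112 times its lowest, and flavopiridol-S5, at 137 times, so such DNA and other causes cannot be told apart for the 12 intervals of DMSO-S2. Read depth alone is argued against by flavopiridol-S6, which had 0.935 times the depth of DMSO-S2 by the lowest local background, whose control is not known, and 0 intervals there. A difference between conditions stays open and was not tested.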

How the results depend on the processing

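Removing high-background intervals or 2 windows of chromosome X and joining peaks within a list were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the lists hold no values per replicate, and leaving out each replicate was not run for the same reason. The alternatives for gene windows and random gene lists were not run either, for want of an annotation on hg19. Flavopiridol-only regions outnumbered DMSO-only regions, and flavopiridol-S5 met a larger share of flavopiridol-S6 than DMSO-S1 did of DMSO-S2, under every alternative run; that difference in shares ranged from 11.5 to 22.3 percentage points. Of 306 values under alternatives, 57 of the main results moved by more than 1.5 times or out of their 95% interval and 131 did not; among the other results 42 moved and 76 did not.

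With a −log10 q of at least 5, the intervals numbered 1627, 1833, 2351 and 3819 in S1, S2, S5 and S6, the median −log10 q was 6.44, 6.46, 7.27 and 8.44, the covered length was 546, 774 and 841 kb in S1, S2 and S5, and the median length was 325 bp in S5. DMSO-only regions numbered 124, the ratio was 7.08, and regions in all lists numbered 243. Regions in S1 without S2, S2 without S1, S5 without S6 and S6 without S5 numbered 1110, 1313, 840 and 2302. Except for the ratio, these follow from fewer and stronger peaks being kept. The share of S2 met by S1 was 27.5% and by S6 43.6%, of S5 met by S1 19.6%, and of S6 met by S1 16.8% and by S5 39.0%; for these shares and the ratio the cause was not tested. With equal numbers, S1 held 5223 intervals over 1373 kb, S1 without S2 numbered 3960 and S5 without S6 2788, by construction. S1, S5 and S6 then met 23.1%, 25.1% and 32.8% of S2, and S1 met 20.6% of S5 and 24.99% of S6, against lists made shorter.

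Reciprocal overlap lowered the shares by construction: S1, S5 and S6 met 18.8%, 18.0% and 22.4% of S2, S1 met 14.2% of S5 and 18.1% of S6, and S5 met 32.9% of S6. A distance of 1 kb raised them to 41.1%, 36.5% and 43.3%, 30.2% and 39.1%, and 53.2% in the same order. Joining peaks up to 1 kb apart gave 213, 258, 185 and 282 intervals of at least 1 kb and 32, 73, 16 and 30 of at least 2 kb in S1, S2, S5 and S6. Without high-background intervals, S5 held 5 intervals of at least 1 kb, and S1, S5 and S6 held 0 of at least 2 kb. In S1 and S5, the lists of lower background, 3 reads could make a peak, against 4 in S2 and S6. How far depth limits each list was not tested.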

Other observations

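The windows below were chosen after the data had been seen, as were all tests in this part except the one on list length. Runs of neighbouring peaks marked a few places in both DMSO lists with fewer intervals in the flavopiridol lists. The largest difference in windows of 100 kb was on chromosome X from 73000001 to 73100000, with 19 intervals in DMSO-S1 and 45 in DMSO-S2, against 1 in each flavopiridol list. The DMSO-S2 intervals covered 20118 bp there and those of DMSO-S1 6455 bp, while flavopiridol-S5 covered 314 bp and flavopiridol-S6 399 bp. A window on chromosome X from 134000001 to 134100000 held 17 and 15 intervals in the DMSO lists and 0 in both flavopiridol lists. On chromosome 11 from 65200001 to 65300000 the counts were 20 in DMSO-S1, 26 in DMSO-S2, 3 in flavopiridol-S5 and 6 in flavopiridol-S6, and the highest −log10 q there, 57.6, was in flavopiridol-S6. In the opposite direction the difference reached at most 3 intervals, in 5 windows, while 24 windows had at least 3 more intervals in both DMSO lists. Once peaks up to 1 kb apart were joined within a list, stretches of at least 5 kb numbered 5 in DMSO-S1, 26 in DMSO-S2, 1 in flavopiridol-S5 and 1 in flavopiridol-S6.

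High-background places recurred across the lists. Of 165 merged high-background regions, 63, or 38.2%, held a peak in all 4 lists, against 4.09% of all merged regions.

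The long intervals of DMSO-S2 were weighed against depth and background. Depth is measured by the lowest local background throughout, and whether inputs entered that background is not known. Flavopiridol-S6, at a similar depth by this measure, held 1 interval of 2 kb or more against 25, which argues against depth for that pair. With peaks up to 1 kb apart joined within a list, the counts were 30 against 73, a smaller gap in proportion. Scaled to the depth of DMSO-S1, 20 of the 24 long regions would hold at least 10 reads at the summit, and 8 of these had no DMSO-S1 interval, although 3 reads could make a peak. At the depth of flavopiridol-S5 the number without an interval was 10 of 17. Neighbouring intervals of a run, as on chromosome 1 from 212781936 to 212796844, were counted separately, so these are not numbers of independent places. Of the 8, those on chromosome 5 at 137801000 and chromosome 1 at 212794354 gained a DMSO-S1 peak when peaks up to 1 kb apart were merged. Over all 25 intervals the median local background was 1 times the lowest of DMSO-S2, which argues against a raised background for the set, though not for the 2 with at least 2 times the lowest, on chromosome 6 at 58776104 with 102 times and on chromosome X at 23801106 with 3.33 times. A difference tied to serum state or inhibitor, and a difference of the DMSO-S2 libraries or of a batch, stay open and were not tested.

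The larger overlap of the flavopiridol lists was weighed in the same way. With 5223 peaks from each list the share of flavopiridol-S6 met by flavopiridol-S5 was 22.3 percentage points above that of DMSO-S2 met by DMSO-S1. With the full lists the difference was 15.2 points. DMSO-S2 was not cut and DMSO-S1 was, so the share of DMSO-S2 met by DMSO-S1 could only fall, and the widening carries no weight. At equal numbers the reverse shares were 46.2% of flavopiridol-S5 met by flavopiridol-S6 and 23.3% of DMSO-S1 met by DMSO-S2. A gap in both directions between lists of equal number argues against list length as its only source. By the lowest background, the depth ratios within the pairs differed by a factor of 1.02, too little for a depth gap to set the pairs apart. In bands of −log10 q below 5, 5 to 10, and 10 and over, the flavopiridol share was higher by 2.16, 9.72 and 9.58 points, and in the reverse direction, S1 met by S2 and S5 met by S6, by 14.5, 30.2 and 4.82 points. The 95% intervals overlapped in the first and the last of these 6, and a band fixes the strength in 1 list of a pair only, so fewer strong DMSO peaks cannot be told apart from other causes. A lower enrichment of the DMSO libraries as a group, a batch or an effect of the inhibitor could each give this pattern, and without values per replicate they were not tested.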
